A study of Mus musculus with 3 samples.

How the data were processed

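Single-cell transcriptomes were measured by droplet-based sequencing (10x Genomics, 3′ v2 chemistry per the labels) in macrophages sorted from the hearts of wild type mice as CD45, F4/80 and CD11b positive cells, with 1 library for each of 3 diets, a control (CD), a high fat (HFD) and a Western one (WD). The diet names come from the series title, and the composition and duration of the diets are not given in the sources used here. According to the labels, flushed hearts were minced and digested with collagenase, and the sort excluded doublets and dead cells.

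The deposited files hold raw UMI counts per gene and barcode as the authors' alignment software wrote them, with no normalization. Per the file headers, the software version was 3.0.1 for CD and HFD and 7.2.0 for WD. Genome build GRCm38 and the Seurat package are named per the submitters' processing notes, without versions, and cell filters, pooling of animals and the counting of intronic reads are not given in the sources used here. The CD and HFD files list 737280 barcodes and 31053 genes, so near-empty barcodes are included. The WD file lists 6885 barcodes and 32285 genes, its smallest barcode has 504 UMIs, and 92 of its barcodes (1.34%) occur in the barcode list of the CD library. The 30406 genes shared by Ensembl ID were kept, 597 of them under differing symbols, and 0.0483% (CD), 0.0507% (HFD) and 0.627% (WD) of the cells' UMIs lay outside them. Positions, exons and introns came from the GENCODE vM21 annotation of GRCm38 with 55450 genes.

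Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrially encoded UMIs. In libraries listing more than 100000 barcodes, a barcode also needed 10% of the 99th percentile of UMIs over the 3000 largest barcodes, which set the threshold at 1674 UMIs in CD and 948 in HFD. The UMI threshold passed 2558 CD, 3185 HFD and 6885 WD barcodes, the gene minimum 2545, 3161 and 6827, and the mitochondrial limit 2458, 2758 and 4868, so that it removed 3.42%, 12.7% and 28.7%. A doublet score after Scrublet, the share of simulated doublets among nearest neighbours, was computed, and the highest scores were removed at 0.8% per 1000 cells, which took out 48 CD, 61 HFD and 190 WD cells. Library totals were 17464149, 16630481 and 79269380 UMIs, of which 73.0%, 52.5% and 90.9% lay in cells past the filters.

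Each library was clustered alone, from counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1. Clusters were named from markers of 19 cell classes. A class needed at least 4 markers at 2-fold or more over the other cells and found in at least 20% of the cluster. Cardiomyocyte and erythroid markers, found in clusters of every class, named none. Macrophage-like clusters needed 6 of 12 macrophage markers, each found in at least 25% of cells, and C1q genes at 25% or more of the macrophage-like level. Clusters with markers of monocytes were called monocyte-like at any C1q level, and clusters that met the macrophage rule with markers of any other class were called mixed. A cluster first called macrophage-like was renamed when its 10 leading genes against the other classes held more markers of another class than of macrophages, at least 3, and stayed unnamed with fewer; the WD mast or basophil-like cluster of 7 cells got its name so, with 3 markers of that class and C1q genes at 32.2%. Clusters much shallower than their library and without a leading gene of their class stayed unnamed, as did clusters with 3 or more cardiomyocyte or erythroid genes among the 10 leading genes. The thresholds for macrophage, mixed and cardiomyocyte-led clusters were set after the clusters had been seen, and the report gives the share of cells they leave out. Macrophage-like cells were clustered again and assigned to 6 subsets, each needing at least 3 and at least 50% of its markers at 1.5-fold or more.

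UMIs were summed over macrophage-like cells and scaled to CPM over the shared genes. The 3 comparisons were HFD against CD, WD against CD and WD against HFD. With 1 library per diet no test between diets is possible and none was made. CPM carry exact Poisson intervals, ratios exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95%, and a count of 0 is given with the level that 3 counts would have. For 22 gene lists (resident macrophage, monocyte-derived macrophage, MHC class II presentation, interferon response, NF-kB and inflammatory cytokine, lipid-associated macrophage, cholesterol synthesis, LXR target, fatty acid oxidation and PPAR target, glycolysis, oxidative phosphorylation, dissociation and immediate early, efferocytosis receptor, complement, growth factor and fibrosis, NRF2 and iron, proliferation, unfolded protein response, sort gate, sex-linked, cytosolic ribosomal protein and mitochondrially encoded genes), the median log2 ratio was taken over members with at least 20 UMIs summed over both libraries. It was set against 10000 random lists drawn from the 100 genes nearest in mean CPM to each member. A member counted as higher or lower at 1.5-fold or more with an interval that excludes 1. In the WD comparisons, list medians and member counts are given after subtraction of the all-gene median. Marker lists, gene lists, the comparisons and the rule for naming single genes were fixed before the data were examined.

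Genes named singly were the 12 highest and 12 lowest ratios against CD, the 5 highest and 5 lowest for WD against HFD, and up to 8 per direction for both diets against CD. They needed at least 100 UMIs over both libraries, at least 50 CPM in the higher library and an interval that excludes 1.5-fold. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes and unnamed gene models were left out. In each list, 2 to 4 members with the largest ratio in either direction are named. Shares of cells with a UMI of 8 marker genes were taken after thinning each cell to 1000 UMIs, with the same share in a non-myeloid class of at least 100 cells as background. Free RNA in CD and HFD was estimated from barcodes with 1 to 50 UMIs at the share that cardiomyocyte and haemoglobin genes imply.

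Alternatives covered a minimum of 1000 UMIs, a mitochondrial limit of 5%, no doublet removal, joint clustering of the 3 libraries, resolution 0.5, thinning to 500 or 2000 UMIs, scaling by the median of ratios or without ribosomal and mitochondrial genes, cells weighted equally, cells thinned before summing, all filtered cells in place of macrophage-like cells, subtraction of free RNA, gene minimums of 100 UMIs and of 1 UMI per library, and a fold of 2. Further alternatives are named in the closing section. The procedure was tested on simulated data, in which the summed counts of a comparison were redrawn as Poisson counts with 200 genes changed by known folds. This redraw follows the counting model of the intervals and holds no variation between cells, clusters or animals. It therefore checks the computation and not the calls in these libraries. The intervals covered the true ratio for 95.2%, 95.6% and 95.4% of genes in the 3 comparisons. Of the genes changed 2-fold, 78%, 84% and 68% passed the size rule for named genes, of those changed 3-fold 98%, 98% and 96%, and no unchanged gene passed.

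Barcodes outside the filters, genes absent from any library and cells of other classes did not enter the main comparisons. Raw reads were not analysed here. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and the random seed was 0.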

Results

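The data describe macrophages from the hearts of wild type mice aged 32 to 34 weeks on a control diet (CD), a high fat diet (HFD) or a Western diet (WD). Cells positive for CD45, F4/80 and CD11b, the surface gate for cardiac macrophages, were isolated by flow cytometry and profiled by droplet-based single-cell RNA sequencing. Each diet is represented by 1 library, the number of mice behind each library is not given in the sources used here, and no difference between diets has a replicate check. The CD library held 17464149 unique molecular identifiers (UMIs, counts of distinct captured transcripts), the HFD library 16630481 and the WD library 79269380. After filtering and removal of the highest doublet scores, 2410 CD, 2697 HFD and 4678 WD cells entered the comparisons. Cells past the quality filters had a median of 4411.5 UMIs and 1620.5 genes in CD, 2708.5 UMIs and 1150 genes in HFD, and 11509 UMIs and 3176.5 genes in WD. All intervals are 95% intervals, which for counts, shares and ratios cover counting error only and for medians over genes the spread between genes.

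Macrophage-like cells, called from Csf1r, C1qa, Mrc1 and 9 further markers, were the largest class in each library. They made up 75.7% (74.0 to 77.4) of CD cells, 75.05% (73.4 to 76.7) of HFD cells and 51.9% (50.5 to 53.3) of WD cells. Endothelial-like cells, which lie outside the sort gate, made up 6.56% (5.60 to 7.62) of the CD and 18.3% (16.9 to 19.8) of the HFD library, and no WD cluster was called endothelial-like. Conventional dendritic-like cells made up 2.86% (2.23 to 3.61) in CD and 4.19% (3.47 to 5.02) in HFD. Fibroblast-like cells, which make the extracellular matrix, were 1.66% (1.19 to 2.25) of CD, 0.593% (0.339 to 0.962) of HFD and 0.770% (0.540 to 1.06) of WD cells, and mural-like cells 1.85% (1.38 to 2.44) of HFD cells. The WD library also held NK-like cells at 3.36% (2.86 to 3.91), neutrophil-like cells at 2.09% (1.70 to 2.55) and mast or basophil-like cells at 0.150% (0.0602 to 0.308). These shares depend on the UMI threshold, which was 1674 in CD, 948 in HFD and 500 in WD. They may also depend on the gap in depth between the libraries, which was not tested.

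**Figure D1:**
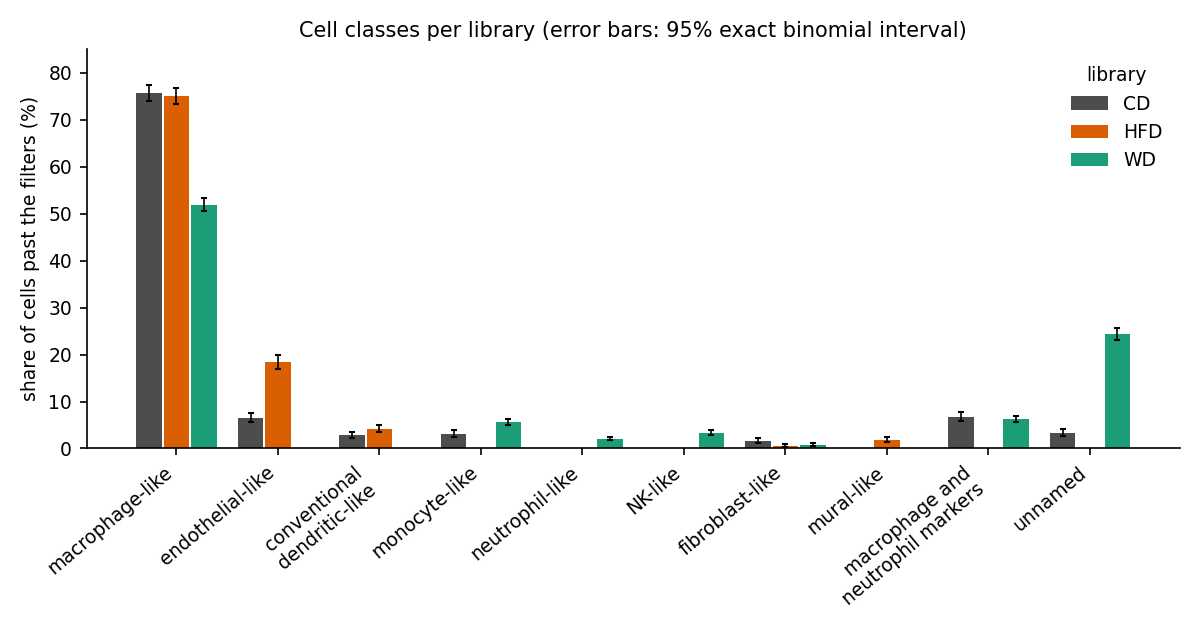
Share of filtered cells (%, vertical axis) in each cell class (horizontal axis) for the CD, HFD and WD libraries, with 95% exact binomial intervals as error bars, for the larger classes. Macrophage-like cells were 75.7% of CD, 75.05% of HFD and 51.9% of WD cells, endothelial-like cells were seen in CD and HFD, and unnamed clusters held 24.3% of WD cells.

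Clusters left out of the macrophage-like class held different shares of each library. Clusters led by cardiomyocyte genes, which stayed unnamed, held 3.32% of CD cells and 18.0% of WD cells. Monocyte-like clusters, recognised by genes such as Ly6c2 and Plac8, held 3.11% (2.46 to 3.89) of CD and 5.58% (4.94 to 6.28) of WD cells. They too carried C1q genes, at 43.4% and 64.6% of the macrophage-like level. Clusters that carried macrophage markers together with neutrophil markers held 6.76% (5.79 to 7.84) of CD and 6.26% (5.59 to 6.996) of WD cells. In WD, further mixed clusters carried markers of conventional dendritic cells (3.51%), T cells (1.18%) and B cells (0.898%), and other unnamed clusters held 6.26%. No HFD cluster was called so, although a subcluster of 11 HFD macrophage-like cells was led by the neutrophil genes S100a8 and S100a9. Counting the cardiomyocyte-led clusters as macrophage-like gave 79.0% in CD and 69.9% in WD, and counting the mixed clusters gave 82.5% and 63.7%; clustering the libraries jointly gave 72.4% in HFD and 77.3% in WD.

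Summed over macrophage-like cells, the libraries gave 9103097 UMIs in CD (1825 cells, median 4370), 6510859 in HFD (2024 cells, median 2887) and 33133848 in WD (2428 cells, median 11570.5). A count of 3 UMIs corresponded to 0.330, 0.461 and 0.0905 CPM (the UMIs of a gene scaled to a common total per library). Transcripts of other heart cells were present in these sums. Cardiomyocyte markers such as Myh6 and Actc1 reached 177 CPM (168 to 186) in CD, 529 CPM (512 to 547) in HFD and 204 CPM (199 to 209) in WD. Endothelial markers reached 114 CPM (108 to 122), 299 CPM (286 to 312) and 29.4 CPM (27.5 to 31.3). Classical monocyte markers stood at 239.9, 246 and 175 CPM. Of these, Ccr2, used here also as a macrophage subset marker, made up 195, 222 and 104 CPM. Neutrophil markers stood at 145, 205 and 159 CPM. Of these, Mmp9, a leading gene of an HFD macrophage-like cluster, made up 31.1, 70.3 and 22.8 CPM. Neither sum is therefore read as RNA of other cells alone. Erythroid markers stood at 42.3, 8.91 and 18.1 CPM. Cardiomyocyte and haemoglobin genes alone, set against near-empty barcodes, would put the share of free RNA in macrophage-like cells at 10.6% in CD and 39.1% in HFD, with no estimate in WD, whose barcodes were already filtered. These shares are too high for the mitochondrially encoded UMIs, which were 50.2% and 46.7% of near-empty barcodes but 3.75% and 4.41% of macrophage-like cells, so no share of free RNA is read from them.

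Within the macrophage-like cells, clusters were assigned to subsets from fixed markers. Clusters with resident markers, including Timd4, Lyve1 and Folr2, the genes of self-renewing heart macrophages, held 33.6% (31.5 to 35.9) of CD, 35.8% (33.7 to 38.0) of HFD and 41.6% (39.6 to 43.5) of WD macrophage-like cells. Those with Ccr2, the receptor that draws monocytes into tissue, together with MHC class II genes held 33.4% (31.3 to 35.6), 39.2% (37.0 to 41.3) and 19.7% (18.2 to 21.4). Proliferating clusters held 5.53% (4.53 to 6.68), 3.51% (2.75 to 4.40) and 5.35% (4.49 to 6.33). Interferon-type clusters held 2.41% (1.76 to 3.22) in CD and 2.51% (1.93 to 3.22) in WD. No HFD subcluster was called so, although an HFD cluster of 21 cells in the first clustering was led by Ifit3, Cxcl10 and Isg15. Lipid-associated clusters held 3.78% (2.95 to 4.76) in CD and 1.48% (1.00 to 2.11) in HFD, and no WD subcluster was called so. Inflammatory clusters were called in WD alone, at 19.9% (18.3 to 21.5), and a CD subcluster of 283 cells, led by Klf4, Ccl7 and Egr1, carried 3 of the 8 markers and stayed without a call. Clusters without a call held 21.2% (19.4 to 23.2), 20.010% (18.3 to 21.8) and 11.0% (9.74 to 12.3). The subset markers themselves differed between libraries, so no direction is read from these shares, and the resident share moved with the settings, to 50.7% in WD at a clustering resolution of 0.5 and to 27.7% with joint clustering.

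Single markers were counted as the share of macrophage-like cells with at least 1 UMI after each cell was thinned to 1000 UMIs, which left out no CD, 25 HFD and 2 WD cells. Thinning evens the depth but not the make-up of the UMIs, which in WD differed with the intron length of the genes, as given below. Differences of WD shares from CD and HFD are therefore not read as differences of diet. The background was the share, thinned alike, in endothelial-like cells of CD (158 cells) and HFD (479 cells) and in NK-like cells of WD (154 cells), where a share of 0 allows up to 1.90%, 0.626% and 1.95%. Before cells too shallow for thinning were left out, these classes had medians of 3256.5, 1706.5 and 6532 UMIs. Timd4, a receptor for dying cells, was found in 9.42% of CD cells (8.12 to 10.9), 9.15% of HFD cells (7.93 to 10.504) and 9.15% of WD cells (8.03 to 10.4) after thinning and in 30.6%, 20.6% and 49.0% without it, and its background shares were 0.633% in CD and 0.649% in WD and no cells in HFD. Lyve1, a hyaluronan receptor, was found in 24.5% of CD cells (22.5 to 26.5), 21.3% of HFD cells (19.5 to 23.1) and 42.8% of WD cells (40.8 to 44.8) after thinning and in 49.8%, 35.9% and 73.4% without it, and its background shares were 0.835% in HFD and 3.25% in WD and no cells in CD. Folr2, a folate receptor, was found in 51.0% of CD cells (48.7 to 53.3), 45.5% of HFD cells (43.3 to 47.7) and 35.7% of WD cells (33.7 to 37.6) after thinning and in 71.0%, 58.3% and 74.0% without it, and its background shares were 3.16% in CD, 5.22% in HFD and 1.95% in WD. Vsig4, a complement receptor, was found in 11.3% of CD cells (9.87 to 12.8), 4.35% of HFD cells (3.50 to 5.34) and 5.32% of WD cells (4.46 to 6.29) after thinning and in 20.5%, 7.41% and 20.8% without it, and its background shares were 0.626% in HFD and no cells in CD and WD. Vsig4 stood at 82.5 CPM in HFD and 72.6 CPM in WD, the other way round from its thinned shares, so no order is read between them.

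Ccr2 was found in 11.9% of CD cells (10.4 to 13.5), 13.2% of HFD cells (11.8 to 14.8) and 5.19% of WD cells (4.34 to 6.15) after thinning and in 26.3%, 20.7% and 18.9% without it, and its background shares were 0.633% in CD, 0.418% in HFD and 10.4% in WD. The NK-like background of WD gives no level of free RNA for Ccr2, which NK cells express themselves. H2-Aa, an MHC class II chain, was found in 65.1% of CD cells (62.9 to 67.3), 81.1% of HFD cells (79.3 to 82.8) and 61.9% of WD cells (59.9 to 63.9) after thinning and in 79.6%, 89.4% and 88.0% without it, and its background shares were 17.1% in CD, 24.0% in HFD and 9.74% in WD. Trem2, a lipid receptor, was found in 29.2% of CD cells (27.1 to 31.4), 19.2% of HFD cells (17.5 to 21.0) and 8.53% of WD cells (7.45 to 9.72) after thinning and in 67.8%, 41.7% and 52.8% without it, and its background shares were 1.90% in CD and 1.25% in HFD and no cells in WD. Il1b, which encodes interleukin 1 beta, was found in 4.66% of CD cells (3.74 to 5.73), 5.95% of HFD cells (4.96 to 7.08) and 17.6% of WD cells (16.1 to 19.1) after thinning and in 11.8%, 11.7% and 42.6% without it, and its background shares were 1.27% in CD, 0.209% in HFD and 1.95% in WD. In summed UMIs, H2-Aa stood at 6148 CPM in CD, 10729 in HFD and 3464 in WD, Trem2 at 403, 268 and 97.6, and Il1b at 67.0, 76.5 and 419.7.

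The comparison of HFD with CD asks how the transcripts of heart macrophages differ with a high fat diet. In macrophage-like cells of the HFD library, MHC class II genes were higher than in the CD library, while inflammatory cytokine genes, immediate early genes and genes of lipid-associated macrophages were lower (2024 against 1825 cells, 1 library each). H2-Aa was 1.75-fold (1.73 to 1.76) higher and Ciita, the master regulator of MHC class II transcription, 2.27-fold (1.98 to 2.61) higher. The chemokine gene Cxcl2, which draws neutrophils, was 13.1-fold (12.1 to 14.4) lower, Ccl3 11.8-fold (9.46 to 14.9) lower and Tnf 6.87-fold (4.87 to 9.98) lower. Spp1, which encodes osteopontin, was 3.58-fold (3.29 to 3.91) lower. The median of all 8152 genes with at least 100 UMIs lay at -0.05 on the log2 scale.

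In the MHC class II presentation list, 7 of 11 members were at least 1.5-fold higher in HFD and none lower, with a median log2 ratio of 0.66, above all 10000 matched random lists. These percentiles are a description of the libraries and no test. Besides H2-Aa and Ciita, the invariant chain gene Cd74 stood at 33055 CPM (32915 to 33194) against 20661 CPM (20568 to 20755), which is 1.60-fold higher, and H2-DMb1, a peptide-loading chain, was 1.72-fold (1.65 to 1.79) higher. Within resident clusters the list median was 0.70, and H2-Aa was 2.01-fold (1.94 to 2.09) higher, Cd74 1.49-fold (1.46 to 1.52) higher and Ciita 2.95-fold (1.76 to 5.11) higher in HFD. In the Ccr2 and MHC class II clusters the median was 0.37, with 1 of 11 members past 1.5-fold and ratios of 1.40-fold (1.38 to 1.42), 1.32-fold (1.31 to 1.33) and 1.76-fold (1.48 to 2.09) for these genes. H2-Aa, Cd74 and other members of the list are among the markers that called these clusters, so the values there are partly set by the call. Summed over all filtered cells in place of macrophage-like cells, 3 members of the list were higher. Gbp3, a guanylate-binding protein gene induced by interferon gamma, was 2.45-fold (2.07 to 2.91) higher. The interferon response list had 3 members higher, 4 lower and 12 neither, with a median of -0.07 (percentile 35.2). Cxcl10 was 3.93-fold (2.80 to 5.62) lower and Ifit2 1.70-fold lower, while Stat2 was 1.62-fold higher.

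The NF-kB and inflammatory cytokine list had 14 of 17 members lower in HFD and none higher, with a median of -1.65, below all matched random lists. Cxcl1 was 30.0-fold (11.5 to 112) lower, from 168 UMIs in CD to 4 in HFD. Il6, which encodes interleukin 6, had 34 UMIs in CD and none in HFD, which allows up to 0.461 CPM. Ccl4, a monocyte chemoattractant, was 4.47-fold (3.98 to 5.03) lower. Immediate early and dissociation-associated genes, induced within minutes of stimulation or tissue digestion, were lower as well, with 13 of 16 members lower, none higher and a median of -1.64, also below all matched random lists. Nr4a1, a nuclear receptor gene, was 5.70-fold (4.00 to 8.35) lower, Ier3 4.73-fold (4.25 to 5.29) lower, the heat shock gene Hspa1b 4.41-fold (3.41 to 5.77) lower and Fosb 3.86-fold (3.43 to 4.36) lower. Within resident clusters the NF-kB list had a median of -0.56 and the immediate early list of -1.14, and Cxcl2 was 9.53-fold (6.999 to 13.3) lower. In the Ccr2 and MHC class II clusters these medians were -1.86 and -2.00, and Cxcl2 was 53.3-fold (40.8 to 70.9) lower. A CD subcluster of 283 cells led by Klf4, Ccl7 and Egr1 and an HFD one of 73 cells led by Cxcl2, Fosb and Fos had no call. Both lay outside these subsets, so the values within subsets also depend on the activated cells left out.

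The lipid-associated macrophage list had 10 of 16 members lower, 1 higher and a median of -0.64, below all matched random lists. The difference was smaller within subsets, with a median of -0.16 in resident clusters (5 of 15 lower, 1 higher) and -0.46 in the Ccr2 and MHC class II clusters (7 lower, 2 higher). After Spp1, the largest ratios were those of the fatty acid carrier gene Fabp5, 2.90-fold (2.59 to 3.26) lower, the lysosomal glycoprotein gene Gpnmb, 2.87-fold (2.38 to 3.47) lower, and lipoprotein lipase, Lpl, 2.62-fold (2.40 to 2.86) lower. The Fabp5 ratio depends on the settings, since its log2 value of -1.54 was -0.77 with cells weighted equally, -0.74 with cells thinned before summing, -0.06 over all filtered cells and 0.35, the other direction, with joint clustering, which took Gpnmb to -3.77. In CD, 1 cluster of 68 macrophage-like cells held 76.4% of all Spp1 UMIs of the library and 95.2% of the Gpnmb UMIs, and in HFD 1 cluster of 29 cells held 82.4% and 93.2%. Most Fabp5 UMIs of the HFD library, 55.1%, lay in an endothelial-like cluster of 406 cells. Fabp4, an adipocyte and endothelial fatty acid carrier, was 2.43-fold (2.20 to 2.67) higher, at 178 CPM against 73.2 CPM. Endothelial markers as a set were 2.61-fold higher in HFD macrophage-like cells (2.42 to 2.82), at 299 CPM against 114 CPM. Fabp4 belongs to that set and made up most of it, so the set is no separate measure. The HFD class also held a subcluster of 22 cells led by endothelial genes, Fabp4 and Sparc among them.

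Among other metabolic lists, LXR targets had 3 of 10 members lower and a median of -0.47. They were led by the lipoprotein gene Apoc1, 1.95-fold lower, and Mylip, 1.73-fold lower. The cholesterol synthesis list had 2 of 16 members higher, among them Idi1 at 1.53-fold, and a median of 0.11. Fatty acid oxidation and PPAR targets had a median of -0.29 and 1 of 13 members lower, Angptl4, an inhibitor of lipoprotein lipase, at 7.99-fold (3.48 to 22.5). Glycolysis genes had a median of -0.39 with 2 of 14 lower, Hk2 at 1.71-fold and Pkm at 1.55-fold. The 20 nuclear genes of oxidative phosphorylation all lay within 1.5-fold, with a median of -0.09. The NRF2 and iron list had 2 of 12 lower, the cystine transporter gene Slc7a11 at 4.84-fold (2.89 to 8.59) and Prdx1 at 1.53-fold, with a median of -0.36. No member of the unfolded protein response list passed 1.5-fold, and its median was 0.17 (percentile 99.9).

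Over all macrophage-like cells, resident macrophage genes differed little, with 1 of 18 members lower, none higher and a median of -0.12 (percentile 17.9). Within resident clusters the median was 0.01, but in the Ccr2 and MHC class II clusters it was -0.81, with 12 of 18 lower and none higher. Resident clusters were called in each library from markers that all belong to this list, so the median within them is partly set by the call. The exception in the pooled cells was Vsig4 (ENSMUSG00000044206, chromosome X, 96247203 to 96293438 on GRCm38), 2.74-fold (2.49 to 3.02) lower. The monocyte-derived list had 4 members lower, 1 higher and a median of 0.02. Chil3, a chitinase-like secreted protein, was 4.21-fold (2.06 to 9.71) lower, the monocyte surface gene Ly6c2 2.18-fold (1.36 to 3.61) lower and Fn1, which encodes fibronectin, 1.72-fold lower, whereas the lysozyme gene Lyz1 was 1.51-fold higher. The efferocytosis list had a median of -0.12 with Cd300lf 3.77-fold (1.96 to 7.97) lower as its single member past 1.5-fold. Complement genes had a median of -0.11 with 3 of 12 lower, among them Cfb at 2.36-fold and C4b at 2.04-fold. The growth factor and fibrosis list went both ways, with 5 of 14 lower and 3 higher around a median of -0.20. Hbegf, an epidermal growth factor family ligand, was 5.94-fold (3.07 to 12.8) lower and Thbs1, which encodes thrombospondin, 4.13-fold lower, while Sparc was 3.74-fold and Mmp9, a gelatinase also made by neutrophils, 2.26-fold (1.95 to 2.63) higher.

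Proliferation genes had 7 of 14 members lower, none higher and a median of -0.57, below all matched random lists, led by cyclin A2, Ccna2, at 3.12-fold (2.19 to 4.57) and Rrm2 at 2.22-fold. Of the sort gate genes, Ptprc (CD45) was 1.22-fold (1.13 to 1.31) higher, Itgam (CD11b) 1.04-fold lower and Adgre1 (F4/80) 1.053-fold lower, with a list median of -0.06. Xist, the female X inactivation transcript, had no UMI in either library, and the Y-linked genes stood at 38.4 against 41.3 CPM for Ddx3y, 46.8 against 47.6 for Eif2s3y, 7.53 against 6.04 for Kdm5d and 7.83 against 10.3 for Uty in HFD against CD. Their median was -0.06. Cytosolic ribosomal protein genes had a median of 0.05 over 78 members, 1 of them higher, and the 13 mitochondrially encoded genes a median of 0.21 with none past 1.5-fold.

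By the rule for naming single genes, the 12 with the highest ratio in HFD against CD began with Tnnt2 (ENSMUSG00000026414, chromosome 1, 135836354 to 135852260), which encodes cardiac troponin T, 4.21-fold (3.60 to 4.94) higher at 98.5 CPM (91.0 to 106) against 23.4 CPM (20.4 to 26.8). Further sarcomere genes followed, Myl3 at 3.54-fold, Myl2 at 3.34-fold, Tnni3 at 2.78-fold and Tpm1 at 2.52-fold. Cardiomyocyte markers as a set were 2.99-fold higher in HFD macrophage-like cells (2.82 to 3.18). Tnnt2, Myl3, Myl2 and Tnni3 belong to that set, so it is no separate measure beside these genes. The ratios of these genes depend on which cells enter, since a CD cluster of 80 cells led by cardiomyocyte genes was left out and HFD had none. The log2 ratio of Tnnt2, 2.07, was 1.45 with that cluster counted, 1.45 at resolution 0.5 and 0.87 over all filtered cells, where Myl2, Myl3 and Tnni3 stood at 0.86, 0.69 and 0.68. The others were Gbp3 (ENSMUSG00000028268, chromosome 3, 142560026 to 142573209), Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576), Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850), Arl10 at 2.32-fold, Got1, an aspartate aminotransferase, at 2.19-fold and Pnisr at 2.07-fold. Among the 12 with the lowest ratio, Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) stood at 83.7 CPM (76.8 to 91.0) against 1100.2 CPM (1079 to 1122), and Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) at 12.9 CPM (10.3 to 16.0) against 152 CPM (144 to 160.5). Gadd45b, a growth arrest and DNA damage gene (ENSMUSG00000015312, chromosome 10, 80930073 to 80932204), was 11.6-fold (8.96 to 15.2) lower. The remaining genes were Ppp1r15a at 6.48-fold, Gadd45g at 5.82-fold, Ier3, Rgs1 at 4.65-fold, Ccl4, Id2 at 3.96-fold, Fosb, Hspa1a at 3.83-fold and Atf3 at 3.73-fold. A mitochondrial limit of 5% left Fabp4 at a log2 ratio of 0.39, and over all filtered cells Lpl, Id2 and Gadd45g stood at -0.51, -1.25 and -1.78 in place of -1.39, -1.99 and -2.54. Without the clusters led by immediate early genes in either library, Cxcl2 was at -5.14.

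**Figure D2:**
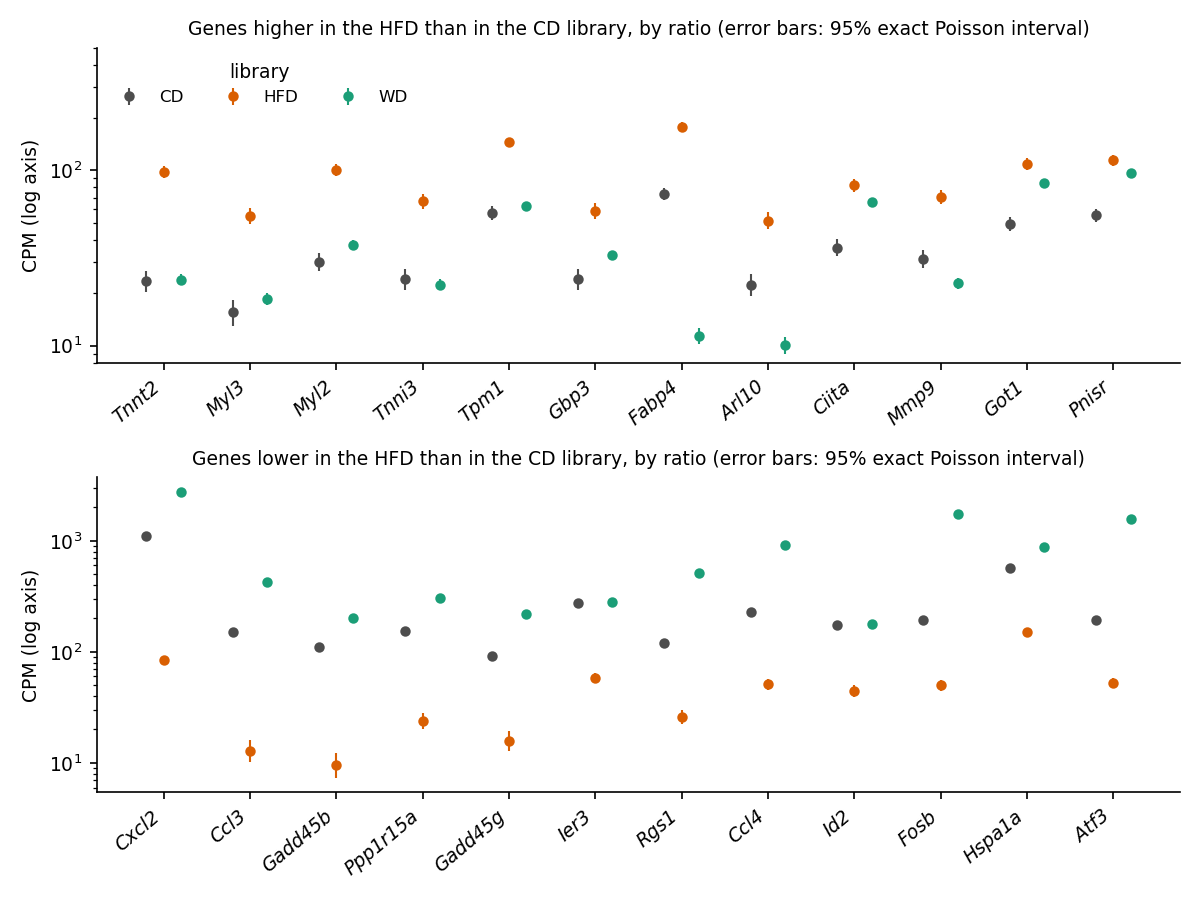
Level in CPM (log axis) in macrophage-like cells of the CD, HFD and WD libraries for the 12 genes highest (top panel) and the 12 lowest (bottom panel) in HFD against CD, with 95% exact Poisson intervals as error bars. Cxcl2 stood at 1100.2 CPM in CD, 83.7 in HFD and 2750.0 in WD, and Tnnt2 at 23.4, 98.5 and 23.8.

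The comparison of WD with CD asks the same of a Western diet. In WD macrophage-like cells, inflammatory cytokine and immediate early genes were higher than in CD, and genes of lipid-associated macrophages and of oxidative phosphorylation were lower (2428 against 1825 cells, 1 library each). Tnfaip3, a feedback inhibitor of NF-kB, was 29.2-fold (24.9 to 34.4) higher and Nlrp3, an inflammasome sensor, 12.6-fold (10.7 to 14.9) higher. Spp1 was 20.3-fold (18.6 to 22.3) lower and Gpnmb 15.7-fold (12.964 to 19.1) lower. The WD library had been processed with another software version, and only 1.34% of its barcodes occur in the barcode list of CD. It differed from CD with intron length over the whole transcriptome, so that diet, kit and processing cannot be told apart for single genes. Genes with over 100 kb of introns had a median log2 ratio of 2.61 (1212 genes), and genes with up to 1 kb one of -0.73 (739 genes), whereas for HFD against CD these medians were 0.05 and -0.07. The median of all 10725 genes was 0.32, so list medians and member counts are given relative to it, and folds of single genes per total UMIs.

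**Figure D3:**
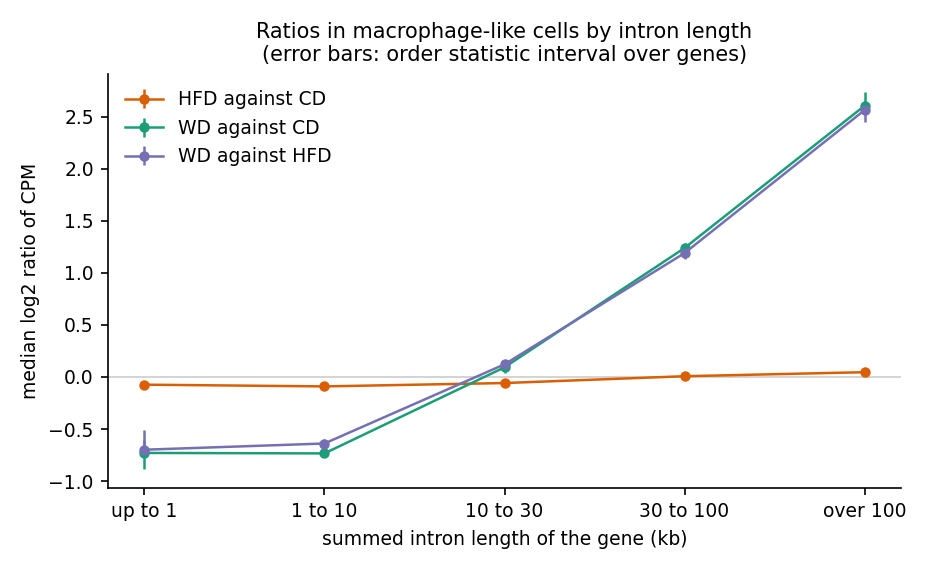
Median log2 ratio of CPM in macrophage-like cells (vertical axis) by summed intron length of the gene (horizontal axis, kb) for the 3 comparisons, with order statistic intervals over genes as error bars. HFD against CD stayed between -0.09 and 0.05, while WD against CD ran from -0.73 to 2.61 and WD against HFD from -0.70 to 2.57.

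The NF-kB and inflammatory cytokine list had 15 of 18 members higher in WD and 1 lower, with a median of 1.90 above the all-gene median (percentile 99.9 of the matched random lists). Il1a, which encodes interleukin 1 alpha, was 33.3-fold (16.8 to 77.4) higher, from 8 UMIs in CD, and Nfkbiz, an NF-kB cofactor, 11.0-fold (10.4 to 11.7) higher. Immediate early genes had 12 of 16 members higher, none lower and a relative median of 0.96 (percentile 99.8). Among them Fosb was 8.99-fold (8.57 to 9.43) higher, the heat shock gene Hspa1b 8.71-fold (7.90 to 9.61) higher, the mRNA decay factor gene Zfp36 8.57-fold higher and Atf3 8.03-fold higher. Within resident clusters, the log2 medians per total UMIs were 3.37 and 2.53, and in the Ccr2 and MHC class II clusters 1.75 and 0.81. A WD subcluster of 631 cells led by Hspb1, Hspa1b and Hspa1a was called resident. The CD subcluster of 283 cells led by Klf4, Ccl7 and Egr1 had no call and lay outside both subsets. The medians within subsets therefore also depend on which activated cells the calls left out. The interferon response list had 5 of 19 members higher and 9 lower around a relative median of -0.58, with Irf1 at 7.14-fold, Stat2 at 4.98-fold and Cxcl10 at 4.67-fold higher.

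The lipid-associated list had 13 of 16 members lower, none higher and a relative median of -1.88, below all matched random lists. Fabp5 was 6.96-fold (6.39 to 7.60) lower, Fabp4 6.43-fold (5.66 to 7.32) lower and Trem2 4.13-fold (3.94 to 4.33) lower. Endothelial markers were 3.90-fold lower in WD macrophage-like cells. Fabp4 is one of them and made up most of their CD sum, so they are no separate measure beside it. A monocyte-like cluster of 261 cells, outside the class, held 47.1% of all Spp1 UMIs of the WD library, 63.3% of Gpnmb and 36.3% of Fabp5, and with joint clustering the log2 ratios of Spp1, Fabp5 and Gpnmb were -1.63, -0.39 and 0.48. All 20 oxidative phosphorylation genes were lower, with a relative median of -1.62 (percentile 0.01, and 0.48 when matched on intron length too, where random lists had a median of -0.90 per total UMIs against -1.30), led by Uqcrc1 at 4.205-fold and Uqcr11 at 3.61-fold. Glycolysis genes had 9 of 14 lower and 5 higher around -1.19, with Pfkfb3, a regulator of glycolytic flux, 13.1-fold (11.0 to 15.8) higher and the enolase gene Eno1 4.29-fold lower. Fatty acid oxidation and PPAR targets had 9 of 14 lower and 2 higher around -0.99, with Angptl4 4.52-fold and Ech1 2.90-fold lower and Pdk4 3.41-fold higher. Cholesterol synthesis genes had 6 of 16 lower and 4 higher around -0.45, with Fdps 2.44-fold lower. LXR targets had 5 of 10 lower and 2 higher around -0.46, with the cholesterol exporter gene Abca1 4.88-fold higher and Apoc1 2.48-fold lower.

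MHC class II genes split, with 8 of 11 lower, 2 higher and a relative median of -1.33 (percentile 2.53). Cd74 was 2.34-fold (2.33 to 2.35) lower and H2-DMa 2.33-fold lower, whereas the activation markers Cd83 and Cd86 were 7.47-fold and 5.60-fold higher. Matched on intron length as well, the MHC class II median lay at percentile 12.6 and that of the resident list at 2.98, while the NF-kB list stayed above and the lipid-associated list below all matched lists. With mixed clusters counted, 5 MHC class II members were lower per total UMIs in place of 8. Resident genes had 11 of 18 members lower, 5 higher and a relative median of -1.25 (percentile 1.84). The mannose receptor gene Mrc1 was 4.18-fold (4.06 to 4.31) higher and the haemoglobin scavenger receptor gene Cd163 3.16-fold higher, while Clec4n was 3.36-fold (3.12 to 3.61) and Vsig4 3.11-fold (2.93 to 3.30) lower. Monocyte-derived genes had 7 of 15 lower and 4 higher around -0.55, with the proteoglycan gene Vcan at 17.4-fold (5.86 to 85.1) from 3 CD UMIs, the decoy receptor gene Il1r2 9.83-fold higher and Ifitm6 2.57-fold lower. Efferocytosis genes had 6 of 12 higher and 4 lower around 0.32, with the engulfment genes Mertk at 16.1-fold (14.3 to 18.3), Dock1 at 14.0-fold and Elmo1 at 11.8-fold higher and the lectin gene Cd209f at 21.4-fold and the scavenger receptor gene Marco at 9.93-fold lower. Members of this list have a median of 55.1 kb of introns, and matched on intron length it lay at percentile 13.3.

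Complement genes had 7 of 12 lower and 2 higher around a relative median of -1.01, with C1qc 2.87-fold lower. Growth factor and fibrosis genes had 7 of 15 higher and 5 lower around 0.53, with the anti-inflammatory cytokine gene Il10 8.24-fold (5.10 to 14.3) and Areg 7.25-fold higher, and Vegfa at 7.14-fold (2.36 to 35.4) from 3 CD UMIs. The NRF2 and iron list went both ways, 4 of 12 higher and 5 lower around -0.09, with Txnrd1 5.65-fold higher and the ferritin light chain gene Ftl1, which shares sequence with its pseudogene Ftl1-ps1, 4.96-fold lower. Proliferation genes had 10 of 14 lower and 1 higher around -1.03, with Rrm2 3.23-fold lower and Mki67 5.31-fold higher. The unfolded protein response list had 3 of 13 higher and 4 lower around -0.18, with Asns at 4.30-fold (1.39 to 21.6) from 3 CD UMIs and Sdf2l1 3.03-fold lower. Of the gate genes, Ptprc was 4.39-fold (4.17 to 4.63) and Itgam 2.36-fold (2.20 to 2.53) higher and Adgre1 1.17-fold lower. Xist had 1 UMI in WD, and Ddx3y was 2.13-fold, Kdm5d 2.33-fold and Uty 9.17-fold higher at 88.0, 14.1 and 94.6 CPM, with Eif2s3y at 44.6 CPM. Ribosomal protein genes had a relative median of -0.82 with 55 of 78 lower, and mitochondrially encoded genes one of 0.47 with 6 of 13 higher. Matched on intron length as well, the ribosomal list turned to lie above most random lists (percentile 99.5), whose median was -0.93 per total UMIs against -0.50. The unfolded protein response list moved from percentile 48.0 to 99.3, the growth factor and fibrosis list from 86.7 to 99.5 and the interferon response list from 13.6 to 87.3, so it too turned. The proliferation list moved from 4.25 to 39.98, with a random median of -0.64 per total UMIs against -0.71, so its lower level is that of genes with like introns, and complement and monocyte-derived genes lay at 35.04 and 48.9.

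Of the 12 genes named as highest in WD against CD, 9 had over 100 kb of introns, compared with 1223 of 11039 genes at this depth. Fgfr2 (ENSMUSG00000030849, chromosome 7, 130162451 to 133123350) had no UMI in CD and 1703 in WD, 51.4 CPM (49.0 to 53.9), which is at least 156-fold higher against the floor of 3 counts. The calcium exchanger gene Slc8a1 (ENSMUSG00000054640, chromosome 17, 81373105 to 81738377) was 552-fold (309 to 1107) higher, and Prkg1, a cGMP-dependent kinase gene, had 1 UMI in CD and a ratio of 957-fold (172 to 37796). Pde7b, Abtb2, Arl15, Rnasek and Adnp had ratios of 314-fold, 241-fold, 149-fold, 148-fold and 118-fold. Galnt2, with 2 CD UMIs, had a ratio of 268-fold (74.1 to 2216), and Camkmt, Tex14 and B3gnt2, with 3 CD UMIs each, had ratios of 237-fold (81.2 to 1152), 223-fold (76.2 to 1081) and 168-fold (57.4 to 816). The 12 lowest had a median of 3.03 kb of introns. Coro1b, an actin regulator (ENSMUSG00000024835, chromosome 19, 4148619 to 4154035), was 26.0-fold (22.6 to 30.0) lower, at 6.79 against 177 CPM. The lectin genes Cd209g and Cd209f (ENSMUSG00000051906, chromosome 8, 4102787 to 4105835) were 25.8-fold (21.1 to 31.7) and 21.4-fold (19.2 to 23.8) lower, the B cell chemokine gene Cxcl13 23.6-fold (19.9 to 28.2) lower and the monocyte chemokine gene Ccl8 7.84-fold (7.53 to 8.17) lower. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), Fabp5, Taf6l at 17.3-fold, Wdr89 at 10.6-fold, Tslp at 7.12-fold and Ftl1-ps1 at 11.9-fold completed the set. With cells weighted equally, the log2 ratio of Cxcl13 was -3.81 in place of -4.56 and that of Spp1 -3.49 in place of -4.34.

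The comparison of WD with HFD sets the high fat and Western diets side by side. Inflammatory and immediate early genes were higher in WD macrophage-like cells than in HFD, and MHC class II, lipid-associated and oxidative phosphorylation genes were lower (2428 against 2024 cells, 1 library each). Cxcl1 was 232-fold (90.6 to 853) higher from 4 HFD UMIs, Tnfaip3 109-fold (76.5 to 162) higher and Cd74 3.74-fold (3.72 to 3.76) lower. Il6 had 1068 UMIs in WD and none in HFD. The all-gene median was 0.34, and genes with over 100 kb of introns had a median of 2.57 against -0.70 for those with up to 1 kb, so the processing of the WD library is open here as well. List values are again relative to the all-gene median.

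The NF-kB list had 16 of 18 members higher, none lower and a relative median of 3.75, above all matched random lists, and Il1a had a ratio of 191-fold (34.1 to 7536) from 1 HFD UMI. The immediate early list had 15 of 16 higher, none lower and a relative median of 2.19, with Hspa1b at 38.4-fold (30.3 to 49.3), Nr4a1 at 35.0-fold and Fosb at 34.7-fold. MHC class II genes had 9 of 11 lower, 2 higher and a relative median of -1.91, with H2-DMa 3.68-fold lower and Cd83 7.70-fold higher. The lipid-associated list had 11 of 16 lower, 1 higher and a relative median of -1.56, with Fabp4 15.6-fold (13.9 to 17.6) lower and Spp1 5.67-fold (5.05 to 6.37) lower. All 20 oxidative phosphorylation genes were lower around -1.47, led by Sdhb at 3.27-fold. Resident genes had 10 of 18 lower and 5 higher around -0.97, with Clec4n 4.23-fold lower and Mrc1 3.87-fold higher. Monocyte-derived genes had 8 of 15 lower and 6 higher around -0.63, with Il1r2 7.70-fold higher. The interferon list had 8 of 19 lower and 5 higher around -0.46, with Cxcl10 18.3-fold (13.5 to 25.6) higher and Irf1 7.48-fold higher. Efferocytosis genes had 6 of 12 higher and 3 lower around 0.75, with Mertk 14.0-fold higher and Cd209f 30.4-fold lower.

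Fatty acid oxidation and PPAR targets had 8 of 14 members lower and 2 higher in WD than in HFD around a relative median of -0.71, with Ech1 2.83-fold lower. Glycolysis genes had 8 of 14 lower and 5 higher around -0.88, with Pfkfb3 15.1-fold and Hk2 4.59-fold higher. Cholesterol synthesis genes had 5 of 16 lower and 2 higher around -0.49, with Fdps 3.05-fold lower, and LXR targets 4 of 10 higher and 1 lower around -0.17, with Abca1 4.87-fold higher. Growth factor and fibrosis genes had 8 of 15 higher and 5 lower around 0.61. Among them Hbegf was 24.0-fold (12.991 to 50.1) higher and Sparc 8.73-fold lower. Endothelial markers were 10.2-fold lower in WD, and most of their HFD sum was Fabp4, itself 15.6-fold lower. Complement genes lay around -0.06, with C1qc 3.11-fold lower. The NRF2 and iron median was 0.29, with Txnrd1 7.82-fold and Slc7a11 6.37-fold higher, the proliferation median -0.31, with Mki67 6.58-fold higher, and the unfolded protein response median -0.44, with Sdf2l1 4.09-fold lower and Atf4 3.06-fold higher. Of the gate genes, Ptprc was 3.60-fold and Itgam 2.46-fold higher and Adgre1 1.11-fold lower, and of the Y-linked genes Uty was 12.1-fold, Ddx3y 2.29-fold and Kdm5d 1.87-fold higher and Eif2s3y 1.049-fold lower. Ribosomal protein genes had a relative median of -0.87 and mitochondrially encoded genes one of 0.15. Matched on intron length, ribosomal, proliferation, interferon and complement genes lay at percentiles 98.9, 93.7, 93.6 and 94.4, all in the upper part of their random lists, oxidative phosphorylation genes at 1.91 and efferocytosis genes at 42.6. The unfolded protein response list moved from percentile 32.4 to 96.6, so it turned.

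The genes named as highest in WD against HFD were Galnt2 and Fgfr2, without a UMI in HFD and at least 128-fold and 112-fold higher against the floor of 3 counts, Prkg1 at 684-fold (123 to 27033) from 1 HFD UMI, the proton pump gene Atp6v0c at 666-fold (285 to 2052) from 5, and Rnasek at 530.2-fold (147 to 4379) from 2. The lowest were Cd209g at 40.8-fold (33.5 to 50.1), Cd209f, Coro1b at 21.2-fold (18.3 to 24.6), Taf6l at 17.9-fold (15.3 to 20.9) and Fabp4.

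**Figure D4:**
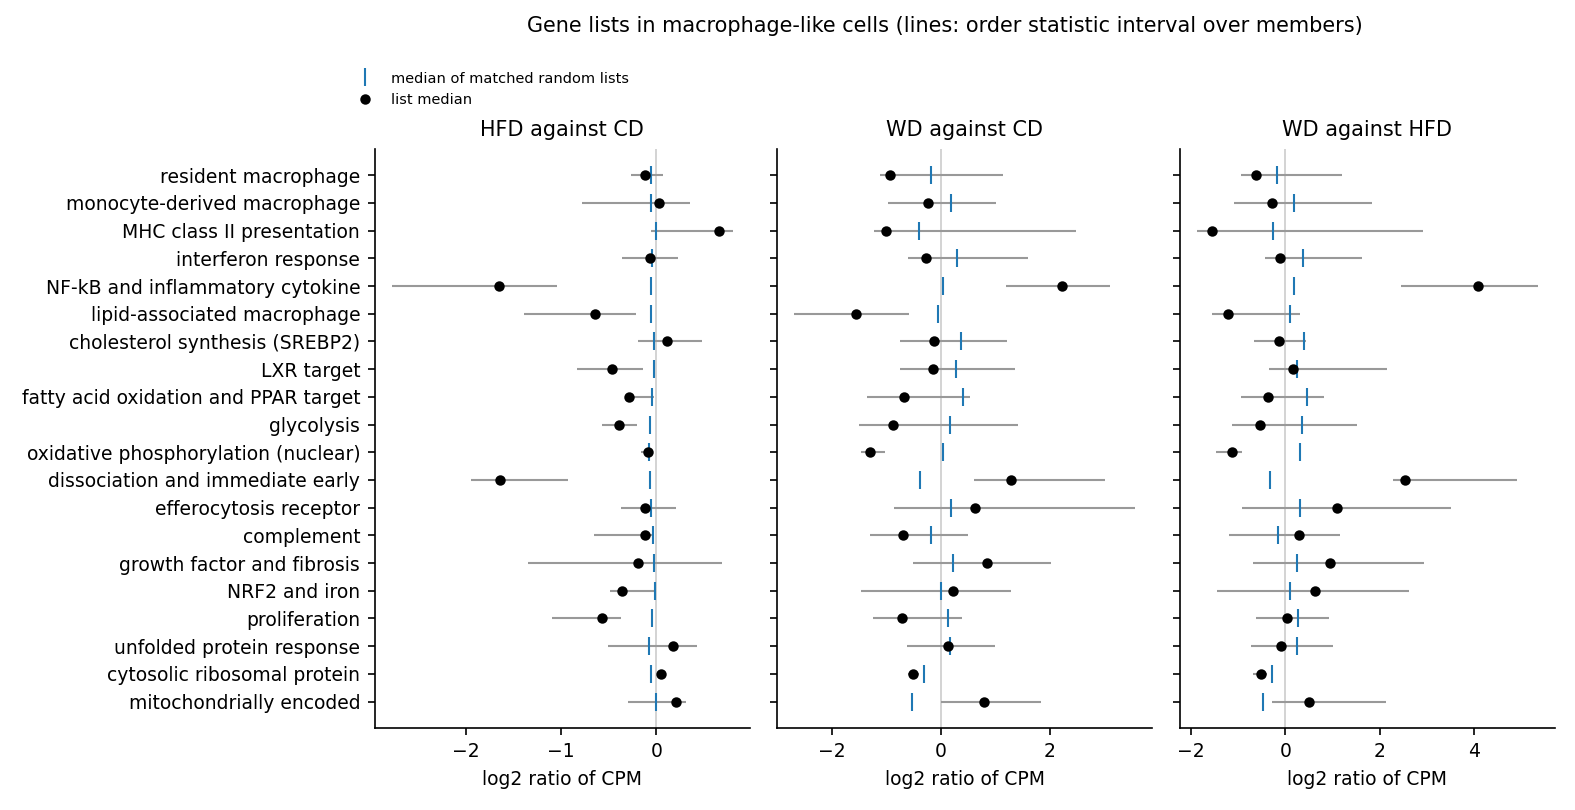
Median log2 ratio of CPM per gene list (points, with order statistic intervals over members as lines) in macrophage-like cells for the 3 comparisons, with the median of matched random lists as blue ticks. The NF-kB list stood at -1.65 in HFD against CD, 2.22 in WD against CD and 4.09 in WD against HFD, before the all-gene median is taken off.

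Against the shared CD library, 5 genes met the rule for being higher in both diets and 8 are named as lower in both. The higher genes were Cyth1, 1.82-fold in HFD and 7.18-fold in WD, Ciita at 2.27-fold and 1.81-fold, Prpf4b at 1.77-fold and 2.24-fold, Pnisr at 2.07-fold and 1.74-fold, and Got1 at 2.19-fold and 1.72-fold. The lower genes were Spp1, 3.58-fold in HFD and 20.3-fold in WD, Fabp5 at 2.90-fold and 6.96-fold, Gpnmb at 2.87-fold and 15.7-fold, Vsig4 at 2.74-fold and 3.11-fold, Rcn3, a calcium-binding protein of the endoplasmic reticulum, at 2.55-fold and 3.37-fold, Birc5 at 2.13-fold and 2.34-fold, the cold-inducible gene Rbm3 at 2.07-fold and 2.002-fold, and Lpl at 2.62-fold and 1.89-fold. Joint clustering turned Fabp5 to a log2 ratio of 0.35 in HFD against CD and Gpnmb to 0.48 in WD against CD, so neither is lower in both diets under that setting. With the all-gene median taken off, the log2 ratios of Ciita, Pnisr and Got1 in WD against CD were 0.54, 0.48 and 0.46, below 1.5-fold, so only Cyth1 and Prpf4b stay past it in both. Intron length was not taken off. Per total UMIs, Ciita (38.8 kb of introns) at 0.86 lay below the median of 1.24 for genes with 30 to 100 kb. Pnisr (18.7 kb) at 0.80 and Got1 (22.3 kb) at 0.78 lay above the 0.09 of genes with 10 to 30 kb. Genes with up to 1 kb and with 1 to 10 kb both had medians of -0.73, and the lower ratios in WD were not corrected for this. Because the HFD and WD ratios use the same CD values, chance in that library enters both, and the number of shared genes is not read further.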

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

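Tests chosen only after the results were seen were the leaving out of each CD cluster in turn, the resident list as a measure of dilution by free RNA, all tests on intron length and on the kit, and the split of S100 counts; the other tests were planned ahead.

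Near-empty barcodes, which entered only the estimate and subtraction of free RNA and no main comparison, carried heart muscle transcripts above the level that a count of 0 allows. In barcodes with 1 to 50 UMIs, cardiomyocyte markers stood at 789 CPM (752 to 828) in the CD library and 1112 CPM (1061 to 1164) in the HFD library. Barcodes removed by the mitochondrial limit carried the macrophage genes C1qa, C1qb and C1qc, at 12470.1 CPM in 87 CD barcodes, 12219 CPM in 403 HFD barcodes and 3412 CPM in 1959 WD barcodes. Genes outside the shared set held 0.627% of the UMIs of WD cells.

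Inflammatory and immediate early genes of macrophage-like cells were lower in the HFD library and higher in the WD library than in CD. Free RNA in HFD is argued against by the subtraction, after which the NF-kB median was -1.66, at a share too high for the mitochondrially encoded UMIs. The resident median of -0.12 (-0.81 in the Ccr2 and MHC class II clusters, where the MHC class II median was 0.37) cannot decide the question. Free RNA lowers a gene only as far as that RNA lacks it, and the resident gene Folr2 was found in 5.22% of HFD endothelial-like cells. For a single activated CD cluster, the NF-kB median stayed at or below -1.31 (-2.59 to -1.03) with each CD cluster left out in turn. No single cluster thus held most of that difference. Without the cluster led by Ifit3, Ifit2 and Isg15, however, it was -1.65 (-2.79 to -0.95), with an upper end above the limit set for the test. By that limit a single cluster is not excluded for the NF-kB list, and for the immediate early list, at -1.22 (-1.61 to -0.42), it stays open. Handling of the cells, such as the time in warm digestion, is consistent with WD against CD, where the immediate early median in fibroblast-like cells was 1.76 on the log2 scale (36 against 40 cells). For HFD against CD, endothelial-like cells gave medians of -0.74 for the immediate early list and -0.86 for the NF-kB list, but macrophage RNA in those droplets may enter these values and a diet may act on every cell type, so handling and an effect of diet, untested in both comparisons, cannot be told apart.

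Gene ratios of WD against CD followed intron length, with a difference of 3.34 in median log2 ratio between genes with over 100 kb and up to 1 kb of introns, against 0.12 for HFD against CD. UMIs from introns counted in the WD library alone are a candidate explanation. Intron length as the source of the list medians is argued against for NF-kB (percentile 100 of random lists matched on CPM and intron length) and lipid-associated genes (percentile 0). It is consistent with the MHC class II median (percentile 12.6), while for resident genes (percentile 2.98) it cannot be told apart from a difference of their own, since that value lies near the edge of the matched lists. Only 1.34% of WD barcodes occur in the barcode list of CD, where a shared kit would put most of them. This argues against the single kit that the labels give, so another kit may also enter the ratios. Kit, software and diet cannot be told apart because each falls on the WD library alone.

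Clusters with macrophage and neutrophil genes together were found in CD (163 cells) and WD (293 cells). Free neutrophil RNA is argued against, since with UMIs split at random, macrophage-like and mixed cells with S100a8 or S100a9 in 1 part carried them in the other part 471-fold (349 to 652) above cells without in CD and 281-fold (247 to 320) in WD, where free RNA would give equal levels. Median doublet scores lay at percentile 82.9 of all cells in CD and 85.4 in WD. Median depths were 1.55-fold and 2.25-fold those of macrophage-like cells. Both met the limits set for pairs of cells in 1 droplet but cannot decide the question. Simulated doublets are sums of cells of the same library, so they lie near any cells with both sets of genes. In CD, without neutrophil-like cells, they draw neutrophil genes mainly from the mixed cells themselves. In WD the mixed cells had a median of 25993 UMIs, macrophage-like cells 11570.5 and neutrophil-like cells 3411, so a pair of median depth would hold fewer. Beside the mixed cells, no neutrophil-like cells were called in CD and 98 in WD. Pairs would thus need single neutrophils to have been lost, which the F4/80 gate may bring about but no values show. The sort excluded doublets by scatter, and macrophages that had taken up neutrophils stay open as an untested explanation.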

How the results depend on the processing

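Alternatives chosen after the data were seen were counting cardiomyocyte-led, monocyte-like or mixed clusters as macrophage-like, leaving out clusters led by immediate early genes, and keeping only genes with at most 10000 bases of introns; the others were planned. Medians here are per total UMIs. Over all settings run, the NF-kB median lay between -2.06 and -1.42 for HFD against CD, 1.90 and 2.49 for WD against CD, and 3.75 and 4.68 for WD against HFD. The MHC class II median lay between 0.56 and 0.79 for HFD against CD, and the lipid-associated median between -0.68 and -0.33. Of 1138 list medians, 1100 moved by less than their interval over members, 14 moved further up, 23 further down, and 1 was counted as reversed. A change of sign counted as a reversal only for lists whose main median lay at the edge of the matched random lists. Medians of other lists could change sign uncounted. The LXR median of WD against HFD did so, from 0.17 to -0.17 with the all-gene median taken off. Of 1125 values of single genes, 868 moved by less than their interval, 60 moved up, 193 moved down and 4 reversed. Of 162 class shares, 130 stayed within their interval, 24 were higher and 8 lower, of 105 subset shares 48 stayed, 28 were higher and 29 lower, and of 168 marker shares 87 stayed, 40 were higher and 41 lower. Of 220 member counts, 207 stayed within 1.5-fold and 13 were lower. All 24 marker shares were lower at 500 UMIs and all 24 higher at 2000 UMIs, by construction. Depth limits the HFD library most, where 3 counts correspond to 0.461 CPM, against 0.0905 CPM in WD.

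The macrophage-like share, 75.7% in CD, 75.05% in HFD and 51.9% in WD, was 77.7% in CD and 69.4% in WD with a minimum of 1000 UMIs, 78.4% and 64.4% with a mitochondrial limit of 5%, 78.2% and 64.8% with no doublets removed, and 79.0% and 49.3% at resolution 0.5. By construction it was 79.0% and 69.9% with cardiomyocyte-led clusters counted, 78.8% and 57.5% with monocyte-like clusters counted, 82.5% and 63.7% with mixed clusters counted, and 62.8% in CD and 70.3% in HFD without the clusters led by immediate early genes. Joint clustering gave 72.4% in HFD and 77.3% in WD. The resident subset share, 35.8% in HFD and 41.6% in WD, was 42.1% and 32.3% with a minimum of 1000 UMIs, 33.2% and 29.7% with no doublets removed, 44.1% and 50.7% at resolution 0.5, and 27.7% in WD with joint clustering. Beyond the changes by construction, the cause was not tested.

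Joint clustering reversed Fabp5 in HFD against CD, from -1.54 to 0.35, and Gpnmb in WD against CD, from -3.97 to 0.48, and gave a resident median of -1.22 in WD against CD; the cause was not tested. Scaling by the median of ratios, which takes off the all-gene median, gave resident and MHC class II medians of -1.25 and -1.33 in WD against CD, and resident, MHC class II and lipid-associated medians of -0.97, -1.91 and -1.56 in WD against HFD. Over all filtered cells, 3 MHC class II members were higher in HFD against CD in place of 7, and the resident median in WD against CD was -1.17; the cause was not tested. Subtracting free RNA reversed the mitochondrially encoded median of HFD against CD to -3.40, Tpm1 to -0.00214 and Myl3 to -0.0133. The subtraction takes off too much, since mitochondrially encoded UMIs are 46.7% of near-empty barcodes and 4.41% of HFD macrophage-like cells, and it fits its share to cardiomyocyte genes, so these values are not read as corrected ratios.

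With a fold of 2 in place of 1.5, fewer members pass by construction, 1 MHC class II member higher and 4 lipid-associated members lower in HFD against CD, 7 resident members lower in WD against CD and 4 in WD against HFD. With mixed clusters counted, 5 MHC class II members were lower in WD against CD in place of 8, and the cause was not tested. Genes with at most 10000 bases of introns leave fewer members, with 0 resident and 4 lipid-associated members lower in HFD against CD, 3 resident, 3 MHC class II and 7 lipid-associated members lower in WD against CD, and 2 resident and 7 lipid-associated members lower in WD against HFD.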

Other observations

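The comparisons of endothelial-like and fibroblast-like cells were chosen after the results in macrophage-like cells were seen, apart from the inflammatory and immediate early lists.

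Endothelial-like cells, which lie outside the sort gate, were compared between the HFD library (494 cells) and the CD library (158 cells). Unfolded protein response genes were higher in HFD, with 6 of 13 members at least 1.5-fold higher, none lower and a median log2 ratio of 0.59, above all 10000 matched random lists. Xbp1, a transcription factor of that response, was 1.83-fold higher (1.40 to 2.42), the chaperone gene Hspa5 1.82-fold higher (1.55 to 2.15), Hsp90b1 1.75-fold and Pdia6 1.60-fold higher. MHC class II genes had 4 of 7 members lower, none higher and a median of -0.63, whereas in fibroblast-like cells (16 against 40) 3 of 4 measured members were higher in HFD, with a median of 2.61, beside C1q genes at 2599.7 CPM in HFD and 234 CPM in CD fibroblast-like cells, so macrophage RNA enters that value. Cd74 stood at 551 CPM in HFD and 1393 CPM in CD, 2.53-fold lower (2.27 to 2.82). Fatty acid oxidation and PPAR targets had 5 of 13 members lower and a median of -0.54, among them Angptl4 at 3.15-fold, the mitochondrial carrier gene Ucp2 at 2.60-fold and Acadm at 2.04-fold lower. The macrophage genes C1qa, C1qb and C1qc were 2.10-fold, 2.80-fold and 2.28-fold lower in HFD endothelial-like cells, which is a measure of macrophage RNA in these droplets. Other foreign RNA differed as well, with cardiomyocyte markers at 592 CPM in HFD and 2099 CPM in CD endothelial-like cells and erythroid markers at 6.84 and 43113 CPM, so the MHC class II and fatty acid oxidation values are not read as changes of the endothelial cells. Nor was the unfolded protein response difference particular to these cells. In fibroblast-like cells 6 of 9 members of that list were higher in HFD, with a median of 1.25. In macrophage-like cells no member passed 1.5-fold and the median was 0.17. Whether foreign RNA enters that list was not tested.

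Immediate early genes of endothelial-like cells had 8 of 16 members lower in HFD and 1 higher, with Fos at 58.7 against 601 CPM, 10.2-fold lower (7.78 to 13.7), and Hsp90aa1 2.01-fold higher. In fibroblast-like cells of HFD against CD, 8 of 11 measured members of that list were lower and none higher, with a median of -0.98. In fibroblast-like cells of WD against CD, 12 of 16 members were higher and none lower.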
